A study of Mus musculus with 6 samples.

How the data were processed

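Total RNA from single dissected branchial arches 1 of mouse embryos at embryonic day 11.5 was biotin-labelled and hybridised to 1-colour Affymetrix arrays, per the labels' protocols and the annotation of the array design. The 6 arrays fall into 3 from Ezh2lox/lox embryos (labelled control) and 3 from Ezh2lox/lox embryos with a Wnt1-Cre transgene (labelled mutant), as the genotype in each sample's title states. The labels call the samples biological replicates with 1 arch per embryo, so that p-values refer to the spread between embryos.

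The deposited values are 1 value per probe set and array on a log2 scale as processed by the authors. The scale was inferred from the values, which run from 2.63 to 14.68 on every array, since no label states it. All 6 arrays shared the same quantiles (25th percentile 4.33, median 5.81, 75th percentile 8.17), which shows that the authors had brought them to 1 common distribution. Background correction, summary method, software and its version are not given in the sources used here. Normalization to 1 distribution removes any difference in total signal between arrays, so that a general shift of all genes could not be seen. Detection calls were not used here, and signals near the low end of the scale hold mostly background. No missing value was present. Pairs of arrays shared between 0.302% and 0.816% of exactly equal values over all probe sets. Correlations between arrays over the 18194 genes tested were 0.995 to 0.998 within groups and 0.988 to 0.992 between groups. No array repeated another. The first principal component held 63.5% of the variance and separated the groups.

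Probe sets were named with the platform annotation of 2016. Of 45101 probe sets, 34958 had exactly 1 gene symbol, 932 had several and 9211 had none. Through their Entrez identifiers 34754 were matched to a gene table of the mouse assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names and for telling autosomal from sex-linked genes, and no coordinates are given because the sources used here name no build. Probe sets with several symbols or none entered no gene-level test. Each of 18194 genes was represented by the probe set with the highest mean over the 6 arrays. For 9012 genes more than 1 probe set existed. Of 585 such genes past the threshold, all probe sets had the same sign in 400 and differed in sign in 185. Among the named genes these were Slc4a1, Ptprc, Acta2, Rian, Inhba, Boc and Cdon. No filter on dim genes was applied, because genes silent in 1 group may be expressed in the other. Where a list member had no probe set with a single symbol it was not analysed here.

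Differences were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as labelled mutant minus labelled control without covariates, two-sided, with Benjamini-Hochberg adjustment over the 18194 genes and a threshold of 0.05. Standard errors are the moderated ones. Gene lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the 28 lists. Camera compares a list with all other genes, whereas fry does not. The lists, the design, the rule for named genes and all alternatives save the one named below were fixed before the data were examined. The lists hold textbook members: PRC2 and PRC1 subunits, Hox genes, Hox cofactors, other developmental transcription factors, arch patterning transcription factors, cartilage, bone, neural crest and glial, neuronal, muscle, epithelial, endothelial, erythroid, macrophage, smooth muscle and pericyte, proliferation, CDK inhibitor, p53 target, imprinted, Wnt, BMP and TGF-beta, Hedgehog, FGF, retinoic acid, endothelin with semaphorin and ephrin, immediate early and heat shock, and housekeeping genes. A list of sex-linked genes served to check embryo sex and was not tested as a list.

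The genes named are Ezh2, the 15 with the largest rise and the 15 with the largest fall among those past the threshold whose groups did not overlap (clone and predicted-gene names left out), the 10 Hox genes with the largest change, the 3 members of every other list with the largest absolute moderated t, and the sex-linked genes. Further list members are named as examples of what a list holds, and were chosen after their values were seen.

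The procedure was tested on simulated data. Of 200 genes changed on simulated arrays with the means and spread of the 18194 real genes and 3 arrays per group, 74.6% of those changed by 0.5 on the log2 scale, 97% of those changed by 1 and 100% of those changed by 2 were recovered, and 5.2% of all 212 calls were false. A further 20 genes, shifted by -0.7 as a list, counted as true calls. Genes were drawn independently from normal distributions with limma's moderated spread, so real data may give lower recovery and more false calls.

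Alternatives tried were a replicate block, quantile normalization on top of the deposited values, centring on the median, leaving out genes not above the 40th percentile on at least 3 arrays, the mean of all probe sets of a gene, every probe set on its own, eBayes with trend and robust settings, array weights, a floor at the 20th percentile of each array, an adjusted p of 0.01, and leaving out each array. Counts over autosomal genes only were added after the data had been seen. A fit with embryo sex as a covariate could not be made, because sex and label coincide on all 6 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.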

Results

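Gene expression was measured in branchial arch 1 of mouse embryos at embryonic day 11.5, the embryonic tissue that gives rise to the jaws and that is built largely from neural crest cells. The embryos carried conditional (lox) alleles of Ezh2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), a histone methyltransferase complex that keeps many developmental genes silent. The 3 embryos labelled mutant also carried, per the labels, a Wnt1-Cre transgene meant to delete Ezh2 in the neural crest lineage, and 3 embryos labelled control carried the lox alleles without the transgene. Each embryo gave 1 arch and 1 array, so that the 6 arrays are separate embryos. Each array held 45101 probe sets, with a median log2 signal of 5.81 and a range of 2.63 to 14.68, and the number of arrays limits the precision of every value. The comparison asks which genes depend on Ezh2 in the crest-derived arch. All changes below are labelled mutant minus labelled control on the log2 scale, and values are mean ± SD with n = 3 arrays unless stated otherwise.

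The targeted gene did not separate the groups. The single probe set of Ezh2 read 11.63 ± 0.15 in the labelled-control arches and 11.66 ± 0.01 in the labelled-mutant arches, a difference of 0.03 with a standard error of 0.09 (limma, Benjamini-Hochberg adjusted p = 0.906). Its position relative to the deleted exons was not determined here, so it checks neither label. The sex-linked genes split the arrays exactly by label. Xist, the RNA that silences an X chromosome in female cells, read 5.62 ± 0.15 in the labelled-control and 13.03 ± 0.10 in the labelled-mutant arches. The Y-linked genes Kdm5d, Eif2s3y and Uty read 9.18 ± 0.06, 9.09 ± 0.15 and 8.18 ± 0.11 in the labelled-control arches, and 2.95 ± 0.13, 3.35 ± 0.38 and 3.23 ± 0.12 in the labelled-mutant arches. Thus all 3 labelled-control arrays had the male pattern and all 3 labelled-mutant arrays the female pattern, and embryo sex and genotype label cannot be separated in any comparison given here. The groups are named by their labels throughout, because several Hox genes described below were high where textbook knowledge of PRC2 places them low.

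**Figure D1:**
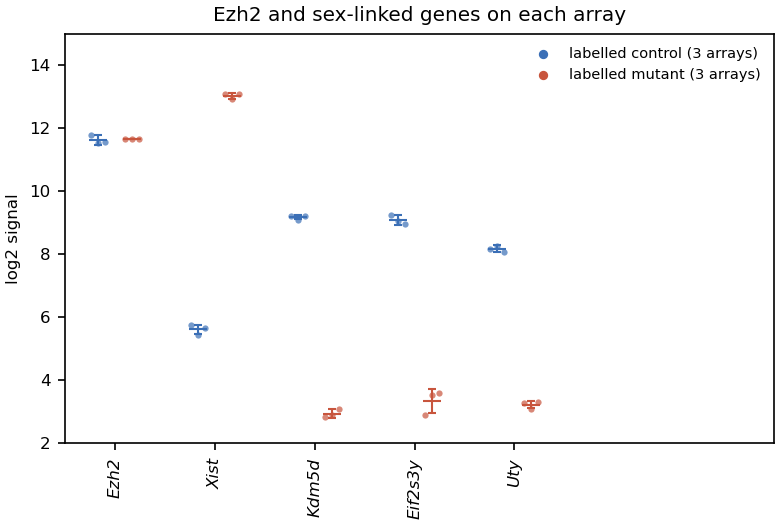
Log2 signal (vertical axis) of Ezh2, Xist and 3 Y-linked genes on each array, with labelled control in blue and labelled mutant in red, 1 point per array and bars for the mean ± SD of 3 arrays. Ezh2 lies at 11.63 and 11.66 in the 2 groups, while Xist and the Y-linked genes separate all 6 arrays by label.

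Far more genes were lower than higher in the labelled-mutant arches. Zic1, a zinc-finger transcription factor of the neural plate border, fell by 7.22, from 10.80 ± 0.29 to 3.59 ± 0.05. Hoxa9 and Hoxa10 fell by 7.07 and 6.71, and the engrailed gene En2 and the LIM homeobox gene Lhx9 fell by 4.25 and 4.19. The labelled-mutant levels of Zic1, Hoxa9, Hoxa10 and Lhx9 lay below the array's 25th percentile of 4.33, so that the size of these falls depends on the low end of the scale. In the other direction, the homeobox gene Gbx2 rose by 2.73 from 5.11 ± 0.05 to 7.84 ± 0.13, and the T-box gene Tbx22 rose by 2.14 from 6.49 ± 0.25 to 8.62 ± 0.29. Of 18194 genes tested, 1007 passed a Benjamini-Hochberg adjusted p of 0.05 with limma, 224 of them higher and 783 lower in the labelled-mutant arches. Of the 243 that also changed at least 2-fold, 25 were higher and 218 lower. At 4-fold or more, 54 were lower and 4 higher. The 3 arrays of each label did not overlap for any of the 1007 genes. Over all genes, 24.9% did not overlap, where chance gives 10%. Of the 1007 genes 967 were autosomal, and of the 618 X-linked genes tested 35 passed, 15 of them higher in the labelled-mutant arches. The count was 551 (89 higher) without labelled-control array 2, 481 (72 higher) without labelled-mutant array 2 and 435 (63 higher) without labelled-mutant array 3, so that the number of rises depended strongly on single arrays. With signals floored at the 20th percentile of each array it was 329 (99 higher). The floor changes no signal above it. A call lost with floored signals thus need not reflect low signals of the gene itself.

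The largest rises after Xist (7.42) included 2 noncoding RNAs of the Dlx loci, Dlx1as (2.86) and Dlx6os1 (1.45). Zmat4 rose by 1.66, the orphan receptor gene Gpr50 by 1.54, Fign by 1.53, Igdcc3 by 1.48 and the nuclear receptor gene Nr5a2 by 1.46. Smaller rises were those of the channel gene Trpm1 (1.22), Dpep1 (1.22), the arginase gene Arg1 (1.21), the Wnt antagonist gene Dkk4 (1.20) and the enolase gene Eno3 (1.19). Among the falls outside the Hox and sex-linked genes, the helix-loop-helix gene Tcf24 fell by 4.78 and Dmrt2 by 4.30, from 9.18 ± 0.14 and 8.74 ± 0.37 to 4.39 ± 0.89 and 4.45 ± 0.50. The standard errors of these changes lay between 0.10 for Xist and 0.36 for Tcf24, and limma's Benjamini-Hochberg adjusted p between 4.53e-09 for Xist and 0.0339 for Igdcc3. Without labelled-mutant array 3, Igdcc3 (limma, Benjamini-Hochberg adjusted p = 0.137), Nr5a2 (0.120), Arg1 (0.0569) and Eno3 (0.0573) no longer passed. Without labelled-control array 2 the same 4 genes also missed the threshold, at adjusted p = 0.131, 0.114, 0.0527 and 0.0565 in that order. Igdcc3 also missed it without labelled-control array 3 (adjusted p = 0.0918) and labelled-mutant array 2 (0.116), Nr5a2 without labelled-mutant arrays 1 (0.0798) and 2 (0.0719), and Arg1 without labelled-mutant array 2 (0.0535), all with limma and Benjamini-Hochberg adjustment. Other probe sets of Zmat4, Trpm1, Igdcc3 and Nr5a2 changed by as little as 0.17, 0.06, 0.12 and 0.03. Nr5a2 missed the threshold with the mean of its probe sets (limma, Benjamini-Hochberg adjusted p = 0.113). Igdcc3 and Nr5a2 missed it with trend and robust settings (0.115 and 0.0630) and with floored signals (0.171 and 0.162), as did Igdcc3 with a replicate block (0.0811).

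Of the Hox genes, which assign position along the body axis and are silent in the normal jaw arch, several were high in the labelled-control arches and low in the labelled-mutant arches, while others were near the low end of the scale in both. Hoxa9 read 11.28 ± 0.37 against 4.21 ± 0.36 (134-fold; limma, Benjamini-Hochberg adjusted p = 7.53e-07), and Hoxa10 read 10.57 ± 0.23 against 3.86 ± 0.07 (104-fold). Hoxc8 fell by 5.81, Hoxb3 by 4.44, Hoxd13 by 4.42, Hoxc10 by 3.94 and Hoxc4 by 3.60. Hoxa11, Hoxb13 and Hoxa2 fell by 3.40, 3.35 and 3.09. Of the 33 Hox genes measured, 22 fell, 0 rose and 11 did not pass, and 27 fell when adjusted over the list alone. The median change was -0.73 and the list as a whole was lower (camera, Benjamini-Hochberg adjusted p = 2.08e-34; adjusted p = 0.0038 with an estimated correlation). All 4 clusters took part. In the HoxA cluster 6 of 9 members fell (median -1.06), in HoxB 7 of 9 (-0.73), in HoxC 5 of 7 (-2.12) and in HoxD 4 of 8 (-0.38). Hoxb1, Hoxd3 and Hoxb7 had log2 changes of -0.17, -0.07 and 0.01 at signals of 3.24, 3.94 and 4.14 in the labelled-control arches, below the array's 25th percentile of 4.33. Others did not pass at clearer signals, with Hoxc6 at 7.05 in the labelled-control and 6.89 in the labelled-mutant arches, Hoxa5 at 7.65 and 7.08 and Hoxa3 at 5.96 and 5.68 (limma, Benjamini-Hochberg adjusted p = 0.526, 0.137 and 0.271). Each of these had further probe sets, and the values given are those of the brightest. With the mean of a gene's probe sets, 25 Hox genes fell, against 22 here. The labelled-mutant levels of Hoxa9, Hoxa10, Hoxc8, Hoxc10 and Hoxa2 lay below the 25th percentile, so their fold changes depend on the low end of the scale. A further probe set of Hoxa9, Hoxa10, Hoxb3 and Hoxd13 gave smaller changes, of -1.51, -0.77, -0.98 and -0.27. The arrays with high Hox levels were also the ones with the male pattern of sex-linked genes. For every other group of genes, whether higher or lower, label and sex pattern coincide as well.

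**Figure D2:**
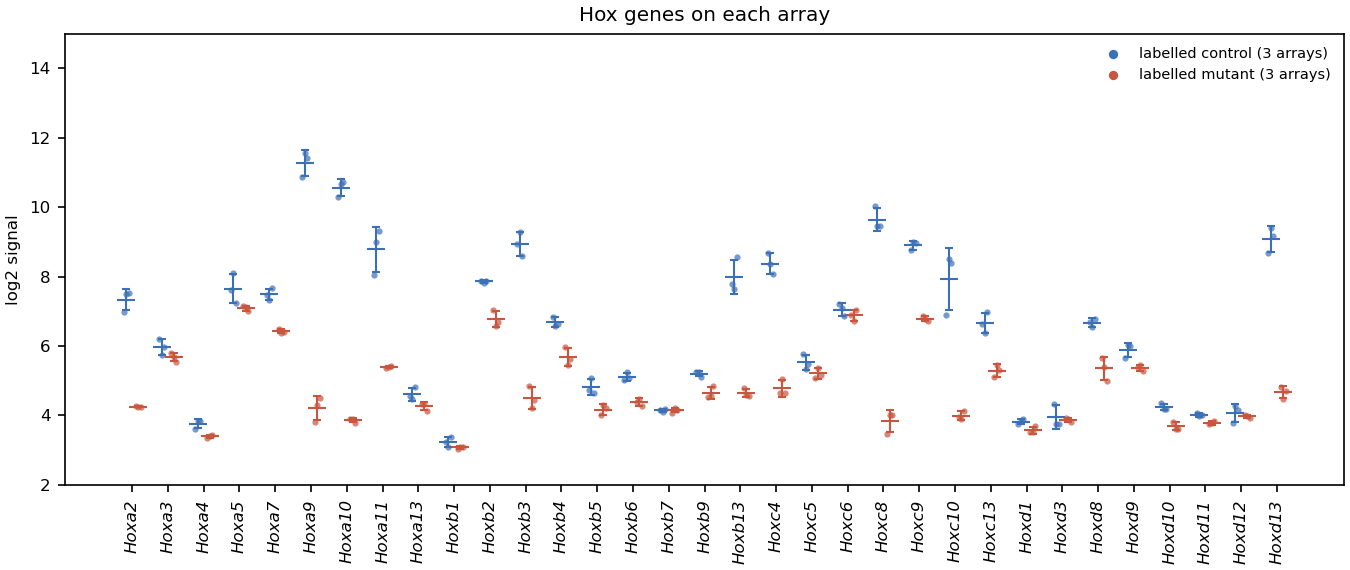
Log2 signal (vertical axis) of the 33 Hox genes measured, in cluster order, with labelled control in blue and labelled mutant in red, 1 point per array and bars for the mean ± SD of 3 arrays. Hoxa9 and Hoxa10 lie at 11.28 and 10.57 in labelled control and at 4.21 and 3.86 in labelled mutant.

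Some of the other developmental transcription factors fell, and Gbx2 rose. En2, a marker of the midbrain and hindbrain border, read 8.59 ± 0.05 against 4.34 ± 0.25 (limma, Benjamini-Hochberg adjusted p = 4.66e-07), and Lhx9 read 8.12 ± 0.26 against 3.93 ± 0.28. The T-box genes Tbx15 and Tbx18 fell by 3.18 and 2.86. Of 44 such factors measured, 13 fell, 1 rose and 30 did not pass, with 17 lower and 4 higher when adjusted over the list alone. The median was -0.10 (camera, Benjamini-Hochberg adjusted p = 1.12e-04), and the call was lost at adjusted p = 0.0884 with an estimated correlation. Among the Hox cofactors, Meis1 fell by 0.95 and Pknox2 rose by 0.71, while Meis2 had a log2 change of -0.32 that did not pass. Other probe sets of Lhx9, Meis1 and Pknox2 changed by as little as -0.28, -0.04 and 0.22. Of 8 cofactors 6 did not pass, 1 rose and 2 fell when adjusted over the list alone, and the list with its median of -0.02 was not called (camera, Benjamini-Hochberg adjusted p = 0.387). Pknox2 missed the threshold without labelled-mutant array 2 (limma, Benjamini-Hochberg adjusted p = 0.0503) and without labelled-mutant array 3 (0.0505).

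Of the transcription factors that pattern the arch itself, more rose than fell. Dlx5, which specifies the lower jaw, rose by 1.18 from 8.95 ± 0.08 to 10.13 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 1.30e-04). Msx2, a homeobox gene of the distal arch, rose by 1.10 and Dlx2 by 0.97. All 6 Dlx genes measured passed, with Dlx6 at 1.00, Dlx3 at 0.79, Dlx1 at 0.67 and Dlx4 at 0.59. Twist2, Foxf2 and Six2 fell by 0.58, 0.51 and 0.60. Of 31 members measured, 12 rose, 3 fell and 16 did not pass, with 13 higher and 8 lower when adjusted over the list alone. The median was 0.15 (camera, Benjamini-Hochberg adjusted p = 0.0163; adjusted p = 0.419 with an estimated correlation). The list also lost its call without labelled-mutant array 1 (camera, Benjamini-Hochberg adjusted p = 0.0748) and with floored signals (0.0578).

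Some cartilage genes rose and some bone genes fell. Sox5, a regulator of chondrocyte differentiation, rose by 1.14 from 6.46 ± 0.14 to 7.60 ± 0.24, Hapln1 by 0.68 and the collagen gene Col2a1 by 0.50 (limma, Benjamini-Hochberg adjusted p = 0.0019, 0.0111 and 0.0098). Another probe set of Sox5 changed by only 0.02. The chondrocyte regulator Sox9 had a log2 change of 0.90 that did not pass. Of 23 cartilage genes 5 rose, 0 fell and 18 did not pass, 10 rising when adjusted over the list alone, with a median of 0.17 (camera, Benjamini-Hochberg adjusted p = 0.0024; adjusted p = 0.118 with an estimated correlation). The collagen gene Col1a2 fell by 0.78, the matrix gene Postn by 1.45 and the growth factor gene Bmp2 by 1.49. Of 16 bone genes 6 fell, 0 rose and 10 did not pass, 6 falling when adjusted over the list alone, with a median of -0.13 (camera, Benjamini-Hochberg adjusted p = 0.0127; adjusted p = 0.374 with an estimated correlation). The members that fell were also Cdh11, Sparc and Col1a1, and all 6 are expressed in mesenchyme outside bone. Sp7, Ibsp and Dmp1, which mark osteoblasts and osteocytes, had log2 changes of 0.10, 0.10 and 0.02. Ibsp and Dmp1 lay below the array's 25th percentile on every array, so their small changes cannot tell whether these markers differ. Sp7 lay above the array's median on every array. Both list calls were lost with floored signals (camera, Benjamini-Hochberg adjusted p = 0.0504 for cartilage and 0.0578 for bone). Without labelled-mutant array 3, Col2a1 (limma, Benjamini-Hochberg adjusted p = 0.0548), Hapln1 (0.0541), Bmp2 (0.0503) and Postn (0.0551) no longer passed, nor did Hapln1 (0.0535), Bmp2 (0.0577) and Postn (0.0679) without labelled-control array 2, Postn (0.0531) without labelled-control array 1 and Col2a1 (0.0547) without labelled-mutant array 2.

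Some muscle, glial and neuronal genes were lower in the labelled-mutant arches, and others did not pass. Myog, a master regulator of skeletal muscle, fell by 2.25 from 8.26 ± 0.34 to 6.02 ± 0.82 (limma, Benjamini-Hochberg adjusted p = 0.0092). Tbx1 and Tcf21, regulators of head muscle precursors, fell by 0.72 and 0.65. Of 17 muscle genes 8 fell, 0 rose and 9 did not pass, 10 falling when adjusted over the list alone, with a median of -0.70 (camera, Benjamini-Hochberg adjusted p = 3.04e-06; adjusted p = 0.217 with an estimated correlation). Myf5, which acts upstream in the muscle lineage, had a log2 change of -0.19 that did not pass. Myog missed the threshold without labelled-control array 2 (limma, Benjamini-Hochberg adjusted p = 0.0535) and Tcf21 without labelled-mutant array 3 (0.0595), with the mean of its probe sets (0.0595) and with floored signals (0.0786). In the neural crest and glial list Zic1 and Ets1 fell by 7.22 and 0.62, the glial regulator Sox10 fell by 0.66, and Snai1, a regulator of crest emigration, rose by 0.92. Of 17 measured, 6 fell, 2 rose and 9 did not pass, 10 lower and 2 higher when adjusted over the list alone, with a median of -0.54 (camera, Benjamini-Hochberg adjusted p = 1.96e-05; adjusted p = 0.185 with an estimated correlation). The neurofilament genes Nefl (-2.56) and Nefm (-2.51) fell, as did the motor neuron gene Isl1 (-0.85), which missed the threshold with the mean of its probe sets (limma, Benjamini-Hochberg adjusted p = 0.0608) and with floored signals (0.0613). Tbx1 (0.0750) and Snai1 (0.0767) also missed it with floored signals. The signals of Tcf21, Isl1, Tbx1 and Snai1 lay above the floor on every array and were unchanged by it. Other probe sets of Tcf21, Ets1 and Isl1 changed by as little as -0.07, -0.06 and -0.10. Of 19 neuronal genes 6 fell, 0 rose and 13 did not pass, 6 falling when adjusted over the list alone, with a median of -0.13 (camera, Benjamini-Hochberg adjusted p = 5.09e-04; adjusted p = 0.0988 with an estimated correlation). Gap43 and Elavl3 had log2 changes of 0.25 and -0.04 that did not pass.

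Several inhibitors of the cell cycle fell, while no proliferation gene passed. Cdkn2a, a classical Polycomb target that restrains the cell cycle, fell by 3.20 from 6.99 ± 0.50 to 3.78 ± 0.20, Cdkn2c by 2.82 and Cdkn2b by 1.80 (limma, Benjamini-Hochberg adjusted p = 1.39e-04, 9.30e-07 and 2.33e-04). The labelled-mutant level of Cdkn2a lay below the array's 25th percentile. Of 7 inhibitors 4 fell, 0 rose and 3 did not pass, 5 falling when adjusted over the list alone, with a median of -0.83 (camera, Benjamini-Hochberg adjusted p = 9.66e-08; adjusted p = 0.0554 with an estimated correlation). Cdkn1a had a log2 change of 0.07. Of 19 p53 targets 4 fell, 0 rose and 15 did not pass, 7 falling when adjusted over the list alone, with a median of -0.09 (camera, Benjamini-Hochberg adjusted p = 0.0023; adjusted p = 0.139 with an estimated correlation). They included Trp53inp1 (-0.89), the cell death gene Pmaip1 (-1.10) and the receptor gene Eda2r (-0.95), whereas Mdm2 was not past the threshold at 0.04. None of 23 proliferation genes passed with limma, and 0 did when adjusted over the list alone, against 3 at an unadjusted p of 0.05, 2 of them higher. Their median was 0.02 (camera, Benjamini-Hochberg adjusted p = 0.482), among them Ccnd2 (-0.37), Ccne1 (0.32) and Rrm2 (0.23). Subunits of the Polycomb complexes themselves mostly did not pass. Bmi1, a subunit of Polycomb repressive complex 1 and a repressor of Cdkn2a, fell by 1.32 from 12.26 ± 0.01 to 10.95 ± 0.15. It was 1 of 16 subunits of that complex to pass, 0 rose, 15 did not pass and 3 fell when adjusted over the list alone, and the list was not called (median -0.04; camera, Benjamini-Hochberg adjusted p = 0.245), with Cbx8 at -0.34 and Cbx6 at -0.27. None of 12 PRC2 subunits passed with limma, also when adjusted over the list alone, against 1 higher and 1 lower at an unadjusted p of 0.05 (median 0.03; camera, Benjamini-Hochberg adjusted p = 0.856), with Phf1 at -0.27, Aebp2 at 0.18 and Eed at 0.15.

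**Figure D3:**
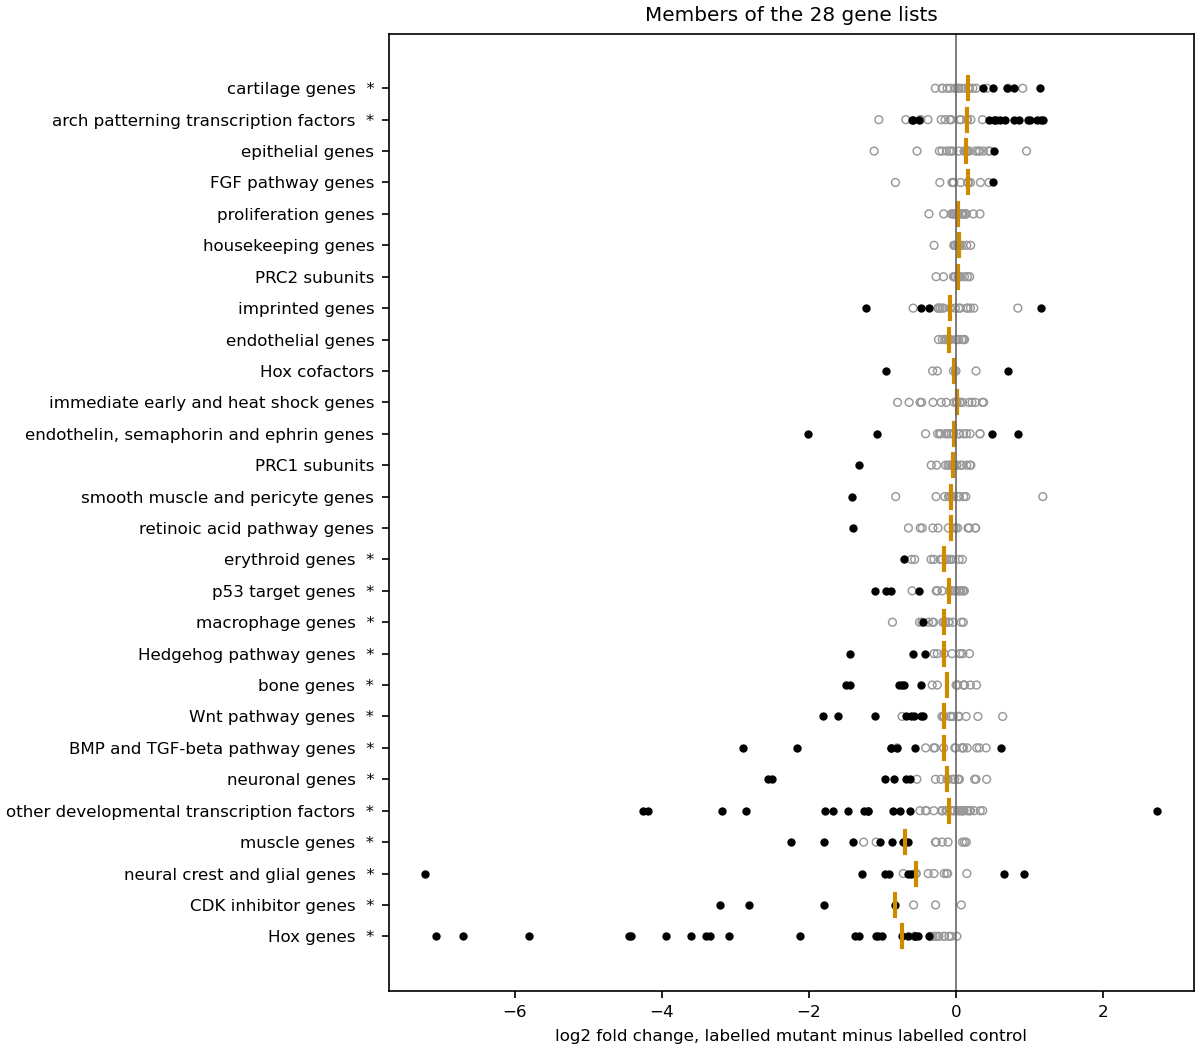
Log2 fold change of each measured member (horizontal axis, labelled mutant minus labelled control) in the 28 gene lists, sorted by mean change. Filled points passed a limma adjusted p of 0.05, open points did not, orange bars are list medians, and an asterisk marks the 15 lists past a camera adjusted p of 0.05, of which 13 were lower and 2 higher.

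Genes of the Wnt, BMP and Hedgehog pathways fell in part. The Wnt receptor gene Lgr5 fell by 1.10, Rspo3, which strengthens Wnt signals, by 1.60, and Wnt5a by 0.61 (limma, Benjamini-Hochberg adjusted p = 0.0021, 0.0031 and 0.0046). Other probe sets of Lgr5, Rspo3 and Wnt5a changed by as little as -0.03, -0.28 and -0.14. Axin2, a transcriptional target of the Wnt pathway, had a log2 change of 0.30 that did not pass. Of 22 Wnt genes 8 fell, 0 rose and 14 did not pass, 9 lower and 2 higher when adjusted over the list alone, with a median of -0.17 (camera, Benjamini-Hochberg adjusted p = 1.12e-04; adjusted p = 0.160 with an estimated correlation). The ligand genes Gdf10, Gdf5 and Inhba fell by 2.90, 0.89 and 0.80, and Bambi, a decoy receptor gene, rose by 0.61. Of 21 BMP and TGF-beta genes 6 fell, 1 rose and 14 did not pass, 7 lower and 1 higher when adjusted over the list alone, with a median of -0.17 (camera, Benjamini-Hochberg adjusted p = 0.0053; adjusted p = 0.407 with an estimated correlation). Of 11 Hedgehog genes, the co-receptor genes Boc (-1.45) and Cdon (-0.58) and the transcription factor gene Gli1 (-0.43) fell, 0 rose and 8 did not pass, 4 falling when adjusted over the list alone, with a median of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.0063; adjusted p = 0.139 with an estimated correlation). The receptor gene Ptch1, a direct target of the pathway, had a log2 change of 0.05. Gli1 missed the threshold without labelled-control array 3 and without each labelled-mutant array, at limma Benjamini-Hochberg adjusted p from 0.0586 to 0.142. In the FGF list Spry1 rose by 0.50, 0 fell and 12 of 13 did not pass, Dusp6 and Fgf10 having log2 changes of 0.33 and 0.45. In that list 2 rose when adjusted over the list alone, and its median of 0.16 was not called (camera, Benjamini-Hochberg adjusted p = 0.236), except without labelled-mutant array 3 (0.0478). Spry1 missed the threshold without either of labelled-control arrays 1 and 2 and without either of labelled-mutant arrays 1 and 2, at limma Benjamini-Hochberg adjusted p from 0.0672 to 0.120.

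Retinoic acid and guidance genes were not called as lists by camera, though both passed fry's mixed test (fry, Benjamini-Hochberg adjusted p = 1.52e-04 and 3.05e-06), and the guidance list passed fry's test for 1 direction (0.0289). Aldh1a2, the main retinoic acid synthesis enzyme of the embryo, fell by 1.40 from 9.10 ± 0.13 to 7.70 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 1.81e-04). It was the only 1 of 14 retinoic acid genes to pass and 2 fell when adjusted over the list alone, with a median of -0.07 (camera, Benjamini-Hochberg adjusted p = 0.236), with Rbp4 at -0.65 and Stra6 at 0.27. Of 21 endothelin, semaphorin and ephrin genes, Epha5 (-2.01) and the semaphorin receptor gene Nrp1 (-1.07) fell, Efnb2 (0.84) and Plxna2 (0.49) rose and 17 did not pass, 3 lower and 4 higher when adjusted over the list alone, with a median of -0.03 (camera, Benjamini-Hochberg adjusted p = 0.587). Of 19 imprinted genes, Phlda2 (-1.23), Sgce (-0.48) and Meg3 (-0.36) fell, Rian (1.16) rose and 15 did not pass, 3 lower and 2 higher when adjusted over the list alone, with a median of -0.08 (camera, Benjamini-Hochberg adjusted p = 0.228). Other probe sets gave -0.36 for Rian, 0.03 for Efnb2 and -0.33 for Epha5. Sgce and Rian missed the threshold without any 1 of labelled-control arrays 2 and 3 and labelled-mutant arrays 2 and 3, Rian also without labelled-mutant array 1, at limma Benjamini-Hochberg adjusted p from 0.0811 to 0.161 for Sgce and from 0.0576 to 0.147 for Rian.

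Most markers of other cell types in the dissected arch did not pass. The leukocyte gene Ptprc fell by 0.46 and was the only 1 of 16 macrophage genes to pass (limma, Benjamini-Hochberg adjusted p = 0.0406), with Mrc1 at -0.87 and Csf1r at -0.46. In that list 4 fell when adjusted over the list alone, and its median was -0.17 (camera, Benjamini-Hochberg adjusted p = 0.0030; adjusted p = 0.486 with an estimated correlation). The call was lost without labelled-control array 3 (camera, Benjamini-Hochberg adjusted p = 0.0696). Of 14 erythroid genes Slc4a1 fell by 0.70, 0 rose and 13 did not pass, 1 falling when adjusted over the list alone, with a median of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.0113; adjusted p = 0.407 with an estimated correlation), with Alas2 at -0.61 and Rhag at -0.56. Of 22 epithelial genes Krt8 rose by 0.52, 0 fell and 21 did not pass, 3 higher and 1 lower when adjusted over the list alone, with a median of 0.14 (camera, Benjamini-Hochberg adjusted p = 0.124), with the signalling gene Fgf8 at 0.96 and Wnt10b at 0.30. That list was called without labelled-control array 3 (camera, Benjamini-Hochberg adjusted p = 1.65e-05). None of 17 endothelial genes passed with limma, also when adjusted over the list alone and at an unadjusted p of 0.05, with a median of -0.10 (camera, Benjamini-Hochberg adjusted p = 0.255), with Erg, Plvap and Tie1 at -0.19, -0.15 and -0.24. Among 13 smooth muscle and pericyte genes Acta2 fell by 1.41, 0 rose and 12 did not pass, 1 falling when adjusted over the list alone, with a median of -0.07 (camera, Benjamini-Hochberg adjusted p = 0.267), with Rgs5 at 1.18 and Pdgfrb at -0.27. Without labelled-control array 1 the endothelial list was called lower, and without labelled-control array 3 the smooth muscle list (camera, Benjamini-Hochberg adjusted p = 0.0289 and 0.0225). Ptprc, Slc4a1, Krt8 and Acta2 each missed the threshold without at least 1 labelled-control and at least 1 labelled-mutant array, at limma Benjamini-Hochberg adjusted p = 0.142, 0.155, 0.169 and 0.144 without labelled-mutant array 3.

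Stress genes and reference genes did not pass. None of 18 immediate early and heat shock genes passed over all genes with limma (2 higher and 4 lower at an unadjusted p of 0.05), with 1 higher and 1 lower when adjusted over the list alone. Their median of 0.01 differed in sign from their mean of -0.08 and from the direction of the list test (camera, Benjamini-Hochberg adjusted p = 0.856), with Egr1 at -0.64, Zfp36 at 0.37 and Hsph1 at 0.36. None of 11 housekeeping genes passed with limma, also when adjusted over the list alone and at an unadjusted p of 0.05 (median 0.03; camera, Benjamini-Hochberg adjusted p = 0.582), with Hprt at 0.20, Pgk1 at 0.14 and B2m at -0.30. Of the 28 lists 15 were called with camera's preset correlation, and the Hox list was the only 1 of these that was also called with an estimated correlation, while 14 were not. Among the 14, the estimate lay below the preset 0.01 for cartilage (6e-04), other developmental transcription factors (0.0041), CDK inhibitors (-0.0028), neuronal (-0.0307) and Hedgehog genes (-0.0242). Correlation among members thus does not account for the loss of these calls. Of 80 genes past the threshold that were followed through every setting, 19 lost the call on leaving out an array and 31 in another setting. Besides those with a loss given above, Gpr50, Trpm1, Dpep1, Meis1, Col1a2, Pmaip1, Eda2r, Phlda2 and Rspo3 lost it with floored signals and Cdon with the mean of its probe sets. Of the 19, all but Col2a1 also lost it with floored signals. Of the 80 genes 44 had more than 1 probe set, and 35 of the 44 had another probe set with under 50% of the change given, among them 7 with one of opposite sign (Slc4a1, Ptprc, Acta2, Rian, Inhba, Boc and Cdon). By fry's mixed test, which asks whether members change in either direction, 20 lists passed a Benjamini-Hochberg adjusted p of 0.05. Of these, 7 were not called by camera, namely the PRC1, Hox cofactor, smooth muscle and pericyte, imprinted, FGF, retinoic acid and guidance lists.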

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

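No test in this part was chosen after its result was seen. One result drew attention because it lies in data that the gene comparison did not use. Of 10143 probe sets with no gene symbol or with several, 96 passed a Benjamini-Hochberg adjusted p of 0.05 in a limma fit over every probe set on its own. Of these, 79 were lower and 17 higher in the labelled-mutant arches, and at 2-fold or more 28 were lower and 1 higher. The share that was lower was 82.3%, and in the same fit 799 of all 965 probe sets past the threshold, these 96 included, were lower. These probe sets are not named here, and no explanation was tested for them.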

How the results depend on the processing

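The counts over autosomal genes were chosen after the data had been seen (966 genes, 233 at 2-fold), and all other settings before. The count of 1007 genes past the threshold was 329 with signals floored at the 20th percentile and 397 at an adjusted p of 0.01. The floor changes no signal above it. Genes as bright as Col1a2 (13.48 in labelled-control and 12.69 in labelled-mutant arches) thus lost the call with unchanged signals, through steps shared across genes. Which step did so was not tested, and the 329 do not count the genes clear of background. Leaving out 1 array gave 435 to 1021, with 551 without labelled-control array 2, 481 without labelled-mutant array 2 and 435 without labelled-mutant array 3, where fewer arrays were fitted. The count at 2-fold, 243, was 113 with the floor and 198 to 280 with 1 array left out. Without dim genes the counts were 959 and 233, with mean probe sets 811 and 177, with trend and robust settings 1032 and 226, with array weights 1300 and 267, and with every probe set on its own 965 and 332. Quantile normalization on top and centring on the median could not test the scaling, since the values were already brought to 1 distribution. Replicate numbers did not pair the samples (correlations of same-numbered deviations -0.21, -0.12 and -0.07), and with a replicate block the counts were 657 (112 higher) and 233, with 15 lists called. A covariate for embryo sex could not be fitted. In all 14 settings with gene-level fits 14 to 25 Hox genes fell and 0 rose, and 12 to 16 lists were called. With the floor the arch patterning (0.174), cartilage (0.242) and bone (-0.342) lists lost their calls at nearly the same mean change, and with array weights the epithelial list (0.111) gained one. With 1 array left out, Ezh2 ran from -0.0233 to 0.117 and was also below 0 without labelled-control array 3 (-0.0033). Mean changes of lists whose call or direction moved ran from -0.0292 (without labelled-control array 2) to 0.0255 for PRC2 subunits and from -0.272 to 0.0764 for immediate early and heat shock genes, whose test pointed up without labelled-control array 2 (0.0764) and without labelled-mutant arrays 2 (-0.0283) and 3 (0.0520). They ran from -0.117 (called without labelled-control array 1) to -0.0088 for endothelial and from -0.0159 to 0.279 (called without labelled-control array 3) for epithelial genes. Macrophage genes ran from -0.358 to -0.111 (call lost without labelled-control array 3), smooth muscle genes from -0.222 (called without labelled-control array 3) to -0.0471, arch patterning genes from 0.144 (call lost without labelled-mutant array 1) to 0.214, and FGF genes from 0.0304 to 0.114 (called without labelled-mutant array 3). For these the cause was not tested. Of 1539 values of 110 named genes besides Ezh2, 1396 kept direction and side of the threshold, 114 lost the call, 29 gained one and 0 turned. These values include named genes without a call, and both scaling settings, in which all 1007 calls stayed. Over all genes fewer calls stayed, with 285 of the 1007 kept with the floor and 432 without labelled-mutant array 3. Of 80 named genes past the threshold 48 kept the call in every setting. Signals near the low end limit what can be said of dim genes.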

Other observations

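The tests of trunk and limb markers, of embryo sex, of transcription factor families and of the members of both transcription factor lists were chosen only after the results were seen, as were the genes named in the next paragraph. The other lists were written before their own values were seen but after the list of 2-fold changes was known.

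Some single genes outside the lists, picked by eye from those that fell, are given here as values only. Of genes known from germ cells, Ddx43 was at -2.23, Meioc at -1.87, Rbm46 at -1.65 and Tex15 at -1.49 (limma, Benjamini-Hochberg adjusted p from 1.29e-04 to 0.0090), and Ddx43 read 6.20 ± 0.33 against 3.97 ± 0.11 (SD, n = 3 arrays each). Of genes known from connective tissue matrix, tenascin C (Tnc) was at -2.23, the proteoglycan genes Lum and Ogn at -1.68 and -1.39, Col14a1 at -1.56, Col6a3 and Col6a2 at -1.35 and -1.22, and the crosslinking enzyme genes Lox and Loxl1 at -1.39 and -1.28. Of genes known from innate antiviral defence, the DNA sensor gene Cgas was at -2.24, Parp12 at -2.39, Shfl at -1.05 and Parp9 at -1.01. Each of these genes passed limma's threshold with all 3 labelled-mutant arrays below all 3 labelled-control arrays, and because they were picked for their falls they say nothing of these groups of genes as a whole, of which others rose (Col2a1 0.50 and Hapln1 0.68 in the cartilage matrix).

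Members of developmental transcription factor families were found among the genes that fell at least 2-fold, also with the Hox genes left out. Of 218 measured members of homeobox, T-box, Sox, Fox, Zic and similar families, 26 fell (11.9%), against 175 of 17940 other genes (0.98%), an odds ratio of 13.7. The families were put together once the 2-fold changes were known, so this ratio restates what was seen, and whether such families are over-represented cannot be told. Zic5 was at -2.62, Onecut2 at -2.64, Dmrta2 at -2.38 and Pou3f3 at -1.84. The same families were also found among the genes that rose at least 2-fold, so they did not mark the falls alone. There, 7 of the 218 members rose (3.21%), against 18 of 17940 other genes (0.1%), an odds ratio of 33.0 with the same limit. These 7 were Gbx2, Tbx22, Dlx5, Dlx6, Msx1, Msx2 and Sox5.

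The high levels of several Hox genes, Zic1, En2 and Cdkn2a in the labelled-control arches run against the textbook effect of PRC2 loss, which raises such targets. A candidate explanation is that the genotype labels were exchanged between the groups: of the members of the Hox list and the list of other developmental transcription factors that passed, 35 of 36 were higher in the labelled-control arches (exact sign test, two-sided, p = 1.08e-09), but this restates the observation, and it was added after the next count was known. Of 54 further textbook Polycomb targets, 4 that passed were higher in the labelled-control and 1 in the labelled-mutant arches (exact sign test, two-sided, p = 0.375). So few calls could not have passed this test whichever way they went, and the list was written once the 2-fold changes were known and holds none of them (largest Otx1, -0.67), so it says nothing of an exchange. Ezh2 itself separates no label, and the exchange stays open. Trunk or limb tissue in the labelled-control dissections may also bring Hox transcripts. The 28 trunk, tail and limb markers had a median change of -0.0685, with 5 lower (Pax1 -2.10, Tbx4 -1.52, Meox1 -1.34, Tbx5 -1.20 and Scx -0.41) and 1 higher (Fgf4 0.43). Among them Tbx5, En1, Cdx1, Cdx2, Cdx4, Lmx1b and Uncx also belong to the list of other developmental transcription factors, whose fall is in question. With this overlap and members that went both ways, the median neither excludes such tissue nor speaks for it. The effect of embryo sex cannot be told apart from that of the label, since the sex-linked genes split 6 of 6 arrays by label. Neither sex nor the genotype as labelled would by itself account for high Hox levels in labelled-control arches (Hoxa9 11.28, Hoxa10 10.57). Hox genes are silent in the normal jaw arch, and these arches lacked the transgene per their labels. For the other changes a biological effect of the genotype as labelled stays open as well.

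With the 6 arrays divided in each of the 10 possible ways into 3 and 3, 1 of the splits, the real one, gave as many as 1007 genes past the threshold, and the highest count among the other splits was 0 (limma, with 292 to 1232 genes at an unadjusted p of 0.05). The splits are too few for a share under 0.05. Every other split also mixes both labels within each group, so that any label difference widens the spread within groups. Low counts in those splits are thus largely built in and do not speak against chance.

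Lower muscle genes in the labelled-mutant arches (median -0.70 over 17 genes) may reflect younger embryos or fewer muscle cells. The labelled-mutant arrays differed among themselves, and the mean change of this list was -0.857 without labelled-mutant array 1 and -0.604 without labelled-mutant array 2. Of 11 early-stage genes, 10 had a change above 0, of which 1 passed (Igf2bp1 0.44) and the largest did not (Trim71 1.24 and Sall4 1.02; limma, Benjamini-Hochberg adjusted p = 0.0525 and 0.0790), and 1 fell (L1td1 -0.94). Their median was 0.2077, between the 0.1 below which younger embryos were to be excluded and the 0.3 they were to reach. Some of the 10 changes above 0 were close to it (Hmga2 0.01, Dppa4 0.02 and Utf1 0.06). The list thus neither speaks for younger embryos nor excludes them. Lin28a (1.12) and Igdcc3 (1.48) had been seen beforehand and were left out of that list. On labelled-mutant array 1 Sall4 and Lin28a read 8.65 and 5.37, against 9.82 and 6.30 on array 2 and 9.46 and 6.44 on array 3. L1td1 did not set array 1 apart in this way, at 6.16 against 6.27 and 6.22. Of 24 further skeletal muscle genes, 19 had a change below 0, of which 3 passed (Tnnt2 -0.74, Myom1 -0.67 and Fndc5 -0.42), and 0 rose past the threshold, with a median of -0.1925, between the -0.1 above which fewer muscle cells were to be excluded and the -0.3 they were to reach. Neither explanation can be told apart from the other or from an effect of the label or of embryo sex.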
